A study of Mus musculus with 6 samples.

How the data were processed

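Small RNA was sequenced from male germ cells of C57BL/6 mice that were wild type (WT) or knockout (KO) for Dnmt3l, the gene of a catalytically inactive partner of the de novo DNA methyltransferases. Per the labels, the P0 libraries came from enriched neonatal germ cells (1 WT, 1 KO) and the P8 libraries from THY1+ cells enriched for spermatogonial stem and progenitor cells (2 WT, 2 KO). RNA of 15 to 36 nt was purified by polyacrylamide gel electrophoresis, and libraries were made with an Illumina small RNA kit, per the labels' protocols. The RNA came from the samples of an earlier long RNA-seq series, which was not used here. The labels give all 6 libraries the same batch. They do not say whether the replicates were separate animals or pools, so p-values measure only the spread between these samples, which may be technical.

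The submitters' processing notes name cutadapt 1.13, FastQC 0.10.1, TopHat2 2.1.1, Bowtie 1.1.1 and bedtools, with the genome build GRCm39. The step each tool was used for, the treatment of reads with several matches, and the source of the intervals are not given in the sources used here. Small RNAs from repeats match many places, so how such reads were placed can set the level of any single interval.

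The authors deposited raw read counts for 1272548 genomic intervals in the 6 libraries, under a name that calls them transposable element counts. Each row is named by its coordinates alone, with a start counted from 0, and 0 rows carry a gene or repeat name. Coordinates are printed here counted from 1 on GRCm39. The intervals measured 110 to 277553 bp (median 946 bp) and overlapped heavily. Their summed length was 4722.4 Mb over 856 Mb of covered sequence, a ratio of 5.52, in 99491 merged regions, the densest of which held 1275 intervals. A read in such a region is counted in several rows, so the column totals are not sequencing depth. The authors also deposited log2 CPM (counts per 1e6 counted reads) for the P8 libraries. These equal edgeR's log2 CPM with trimmed mean of M-values (TMM) factors over the 4 P8 columns and a prior count of 2, to within 4.8e-14.

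To count each read once where possible, a set of non-overlapping intervals was chosen by the mean CPM over all 6 libraries, without regard to genotype, taking the interval with most reads first. Beside repeat subfamilies, the planned level was every deposited interval, and the non-overlapping set was added after the overlap had been seen. It leads the text, and both are given. It held 88351 intervals with a read. The 6 libraries had 4370403 to 6119823 reads in this set and 37285648 to 64009619 counts over all intervals. CPM values in the text are scaled by TMM factors over the 6 libraries, and P8 log2 fold changes come from a fit to the P8 libraries alone.

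KO and WT at P8 were compared with edgeR 4.0.16 (R 4.3.3), using filterByExpr, TMM, glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg (BH) adjustment and a threshold of 0.05. The age contrasts and the genotype by age interaction came from a 4-group fit to all 6 libraries. In that fit the P0 groups of 1 library are assumed to vary like the P8 pairs. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Where a group had few reads they can be narrower than counting error alone, so counting intervals are the better guide there. The P8 fit had 2 residual degrees of freedom, a prior of 10 and a common biological coefficient of variation of 10.9%. At P0 there was no test. Ratios of scaled reads carry exact conditional binomial 95% intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. A fold against a group with 0 reads is a lower bound against a floor of 3 reads over that group.

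On simulated counts with 200 changed intervals, the P8 fit on the non-overlapping set recovered 55% of 2-fold and 90% of 4-fold changes, and the P8 fit on all intervals 38% and 82%. The age contrast recovered 46% and 82%, and the interaction 10% and 57%. In these simulations 5, 3, 7 and 2 unchanged intervals were called, in that order. The changed intervals were drawn from those above a minimum expected count and were far fewer than the calls in the P8 data. Recovery in the data may therefore differ. The 2 WT P8 libraries differed by more than sampling noise (chi-square per degree of freedom 3.24), as did the 2 KO P8 libraries (3.76). Neither pair was therefore a repeated deposit of 1 library, and each library was kept as a replicate, although separate preparations of the same RNA would also differ by more than sampling noise.

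Intervals are named by a rule fixed before the data were examined. At P8 these are the 10 highest and 10 lowest log2 fold changes with an adjusted p under 0.05, a mean of at least 10 CPM and both KO libraries on the same side of both WT libraries. The 5 highest and 5 lowest are named for all deposited intervals at P8 under the same limits, with CPM taken over the counts of all intervals. The 5 highest and 5 lowest are also named for the age contrasts and for the interaction, with the same adjusted p and a mean of at least 10 CPM. At P0 they are the 10 highest and 10 lowest ratios with at least 100 reads, at least 2-fold apart, and an interval that excludes 1. The rule was written for repeat subfamilies and is applied to intervals. Its limit to certain repeat classes was dropped, because the rows carry no repeat name. Regions of neighbouring intervals were defined after the values were seen, as at least 3 intervals changed at least 2-fold in the same direction, at a mean of at least 10 CPM, with gaps of up to 50 kb.

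Alternatives were DESeq2 size factors, total counts without a scaling factor, no filter beyond 1 read, the DESeq2 1.42.0 Wald test, each P8 replicate left out, the replicate number as a block, and a 4-group fit. Alternatives chosen after seeing the data were 1 interval per merged region, a set without the 100 intervals with most reads, a 2-fold minimum, and limma 3.58.1 with a trend on the deposited log2 values. Sums per repeat subfamily, tests of repeat lists and repeat class shares had been planned. They were not run, because no GRCm39 repeat or gene annotation was used here and coordinates were not converted between builds. For the same reason no gene is named for an interval, and the level of Dnmt3l itself was not analysed here. Summaries and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.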

Results

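Small RNAs of 15 to 36 nt were profiled in 6 libraries of Dnmt3l WT and KO mouse germ cells, with 1 library of each genotype at P0 and 2 of each at P8. The size range takes in microRNAs and piRNAs, the germline small RNAs that guide the silencing of transposons. The series concerns the relation between DNMT3L and piRNA production in postnatal spermatogonial progenitors. The non-overlapping set held 6118894 reads in WT P0 and 4370403 in KO P0. It held 6119823 and 5561838 reads in the WT P8 libraries, and 4908024 and 4839935 in the KO P8 libraries. The 100 intervals with most reads in each library took 17.3% of the reads in WT P0 and 18.6% in KO P0. They took 28.5% and 27.9% in WT P8, and 31.2% and 30.4% in KO P8. Replicates at P8 had a Pearson correlation of log2 CPM across 9685 intervals of 0.985 in WT and 0.981 in KO, where intervals are not independent replicates.

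Loss of Dnmt3l was accompanied at P8 by higher small RNA levels at many loci and lower levels at many others, with near-complete loss at a few loci that were abundant in WT. Small RNA levels were higher in KO at 5227 of 23200 tested intervals and lower at 4655. The difference was at least 2-fold at 3292 of the higher and 2111 of the lower intervals. Among the 9685 intervals with a mean of at least 10 CPM, 1282 were at least 2-fold higher and 843 at least 2-fold lower. These counts come from edgeR's quasi-likelihood test with BH adjustment on 2 KO and 2 WT libraries. With total counts in place of TMM factors the same test called 4715 higher and 5368 lower, so that the share of higher intervals among the calls went from 52.9% to 46.8%.

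**Figure D1:**
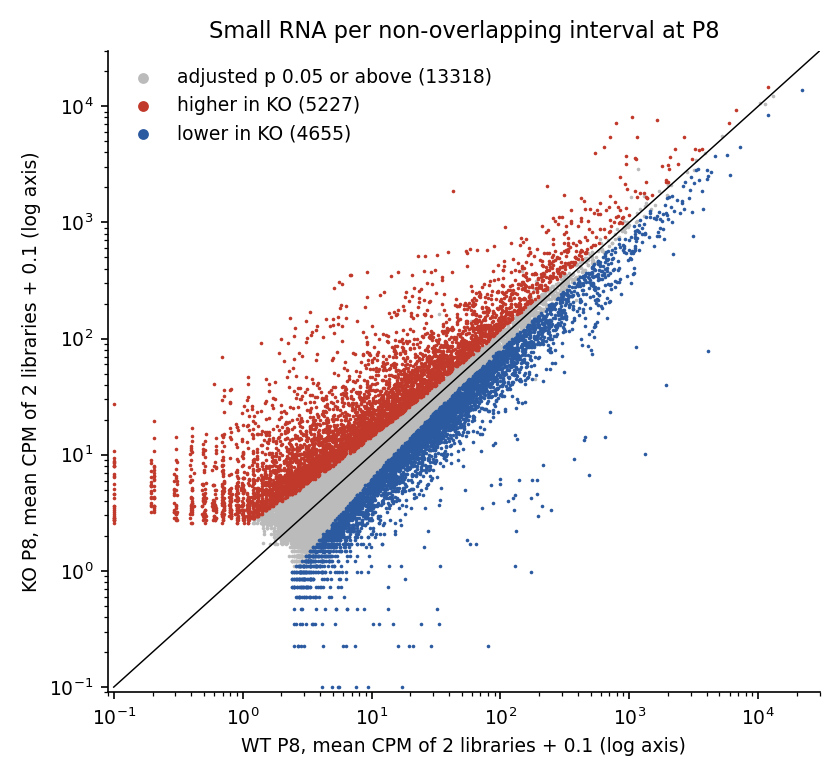
Mean CPM of the 2 WT P8 libraries (x axis) against that of the 2 KO P8 libraries (y axis), both on log axes after adding 0.1, with 1 point per tested non-overlapping interval. The 5227 intervals higher in KO (red) and the 4655 lower in KO (blue) lie on either side of the line of equal levels, with grey points at an adjusted p of 0.05 or above.

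Several of the deepest losses lay together on chromosome 17. In a 70.8 kb region at chr17:27512805-27583649, which was picked for its changed intervals, all 7 non-overlapping intervals with a read, 6 of them changed, summed to 7597 ± 337 CPM in WT P8 and 129 ± 4.44 CPM in KO P8 (SD, n = 2 each), a 58.9-fold difference. At P0 these intervals summed to 169 CPM in WT and 116 CPM in KO. Of the 10 lowest log2 fold changes, 4 were in this region. The interval at chr17:27581941-27583649 had 800 reads in WT P8 and 1 read in KO P8, with a log2 fold change of -9.02 and a ratio of 646 (95% counting interval 116 to 25540). The interval at chr17:27512805-27525382 fell from 1317 ± 67.6 CPM in WT to 9.97 ± 1.72 CPM in KO (SD, n = 2 each), with a log2 fold change of -7.01 ± 0.12 (SE). The interval at chr17:27579186-27581142 had a log2 fold change of -7.55, and that at chr17:27528327-27528579, with 2 reads in KO, was 133-fold lower (36.5 to 1101).

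Deep losses also occurred at intervals of chromosomes 15, 9, 5 and 2. At chr15:74512551-74516001 the level was 248 ± 18.0 CPM in WT P8 and 3.24 ± 1.04 CPM in KO P8 (SD, n = 2 each), a log2 fold change of -6.22. At chr9:67623464-67630476 it was 488 ± 55.6 CPM in WT and 6.61 ± 0.558 CPM in KO, a log2 fold change of -6.17. Intervals with 1 and 2 reads in KO were 232-fold lower at chr5:149750553-149755275 (95% counting interval 41.3 to 9181) and 95.6-fold lower at chr2:92375693-92376044 (26.2 to 794). The remaining 2 of the 10, chr2:98492576-98497677 (log2 fold change -6.95) and chr14:3050005-3054056 (3 reads in KO, ratio 85.8, 29.1 to 418), were also far lower in KO at P0 and are described with that comparison. Adjusted p for the 10 lay between 3.58e-12 and 2.96e-07 in edgeR's quasi-likelihood test with BH adjustment, and all 10 were lower in both KO libraries than in both WT libraries.

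The 10 highest log2 fold changes were spread over several chromosomes, at intervals with a mean of at most 6.71 CPM in WT P8. The interval at chr5:12205541-12213229 had 0 reads in WT P8 and 27.2 ± 3.41 CPM in KO P8, at least 90.0-fold higher. Levels at chr15:29984069-29984850 were 0.596 ± 0.247 CPM in WT P8 and 69.5 ± 8.16 CPM in KO P8 (SD, n = 2 each), a log2 fold change of 6.81 ± 0.26 (SE). The highest KO levels among the 10 were on chromosome 2. Levels at chr2:148247981-148250908 were 6.71 ± 1.14 in WT and 355 ± 0.483 CPM in KO (log2 fold change 5.75). At chr2:179953151-179965598 they were 5.48 ± 1.79 and 305 ± 1.67 CPM (log2 fold change 5.81). These are differences between genotypes at P8 and need not be gains with age in KO. The P0 libraries had 8.31 CPM in WT and 74.2 CPM in KO at the former, and 163 and 267 CPM at the latter. At chr11:29075348-29075560 the level was 5.01 ± 0.537 CPM in WT P8 and 271 ± 26.0 CPM in KO P8, a log2 fold change of 5.78. The other log2 fold changes were at chr16:70340245-70340366 (6.29), chr2:17756439-17756669 (6.14), chr11:51399184-51425148 (6.09), chr12:67882204-67883157 (5.86) and chr9:102369139-102396566 (5.73). Adjusted p for these 10 lay between 4.15e-11 and 9.65e-08 in the same edgeR test with BH adjustment.

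Some changed intervals lay next to each other. By a definition set after the values were seen, there were 36 regions of neighbouring changed intervals, 22 higher and 14 lower in KO, against a median of 17 and at most 31 in 1000 random placements. These placements treat intervals as independent, which pieces of the same locus are not, so no p-value is given. Region levels are sums over all non-overlapping intervals with a read, changed or not, in regions that were picked for their changed intervals. Among the lower regions, chr15:59134580-59169663 had 452 ± 50.0 CPM in WT P8 and 14.2 ± 0.0616 CPM in KO P8, a 31.8-fold difference. The region at chr2:92375693-92448174 was 23.2-fold lower in KO, that at chr17:66514999-66583663 8.31-fold, and that at chr10:69930395-70031732 4.99-fold. Among the higher regions, chr9:102369139-102423443 had 28.5 ± 0.336 CPM in WT P8 and 726 ± 28.8 CPM in KO P8, a 25.5-fold difference. The regions at chr8:13745616-13799145, chr16:31180760-31418824 and chr11:94017473-94167870 were 10.3-fold, 6.99-fold and 4.04-fold higher. The higher region with most reads in WT, chr18:38276932-38415565, had 943 ± 27.8 CPM in WT and 2749 ± 16.5 CPM in KO, a 2.91-fold difference. These SDs are over 2 libraries each.

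**Figure D2:**
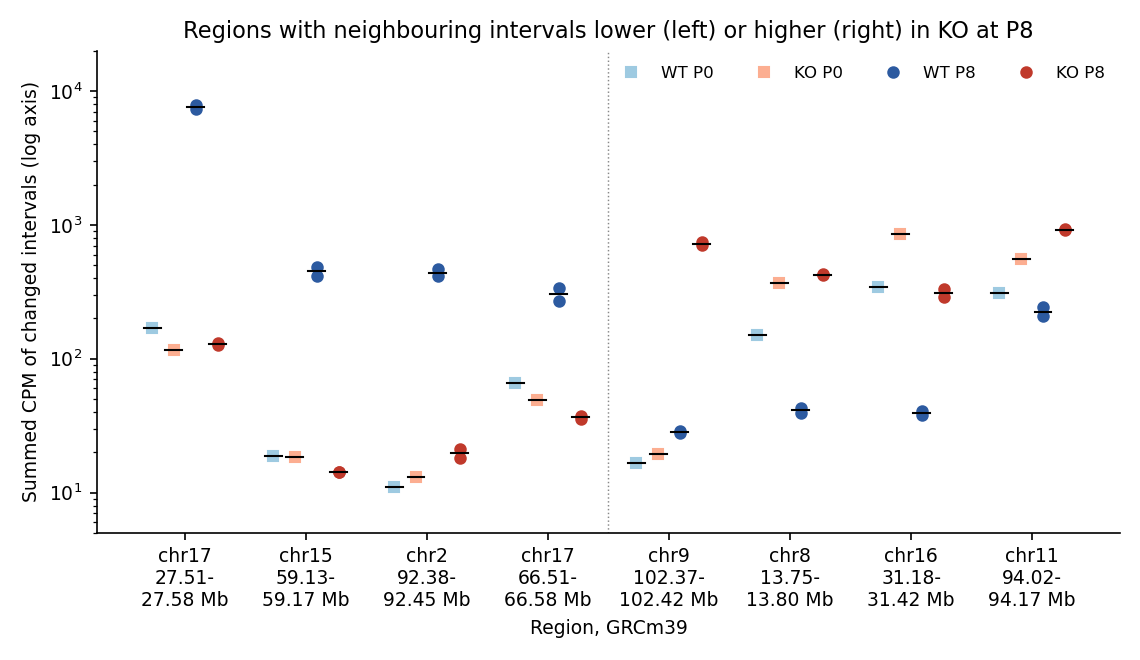
CPM summed over the changed intervals of each region (y axis, log) in every library, for the 4 regions with the largest fold lower in KO at P8 (left) and the 4 with the largest fold higher (right). Squares are the single P0 libraries, circles the 2 P8 libraries of each genotype and bars the group means, and the changed intervals of the region at 27.51 Mb of chromosome 17 sum to 7588 CPM in WT P8 against 129 CPM in KO P8.

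The test run on every deposited interval, many of them overlapping, called 56613 higher and 51940 lower in KO of 247651 tested. Among called intervals with a mean of at least 10 CPM of all interval counts, and both KO libraries on the same side of both WT libraries, the highest log2 fold change was at chr16:31962115-31963476, with 15 and 14 reads in WT P8 and 2746 and 2839 in KO P8, at 7.79. An overlapping interval at chr16:31948382-31963417 had a log2 fold change of 6.79. Overlapping intervals at chr7:83577016-83577193 (5.72) and chr7:83577108-83577384 (5.65), and chr2:179953151-179965598 (5.69), were the rest of the 5 highest under these limits. The 5 lowest under them, from -7.67 to -6.56, were intervals between 27510831 and 27581142 on chromosome 17, 4 of which overlapped each other. Adjusted p for these 10 was at most 5.28e-11 in edgeR's quasi-likelihood test with BH adjustment.

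For the P8 comparison, DESeq2 called fewer intervals of the non-overlapping set (3199 higher, 2440 lower), and without a read filter edgeR called 3516 and 2349. Leaving out WT P8 replicate 1 gave 3569 higher and 3029 lower, and leaving out WT P8 replicate 2 gave 3669 and 3057, with 5227 and 4655 from all libraries. Over all deposited intervals DESeq2 gave 32216 and 26109, no filter 31385 and 24609, and leaving out WT P8 replicate 1 34031 and 28559.

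At P0, with 1 library per genotype and therefore no replicate check, the most extreme differences were lower levels in KO. Of 14108 intervals with at least 100 reads, 1392 were at least 2-fold higher in KO and 607 at least 2-fold lower, with counting intervals that exclude 1. With total counts in place of TMM factors these were 1187 and 882, so that the share of higher intervals went from 69.6% to 57.4% and the median log2 ratio from -0.11 to -0.22. These counts compare 2 libraries, not the genotypes.

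The interval with most reads among the 10 lowest ratios at P0, chrUn_JH584304v1:56548-114452, had 8386 CPM in WT P0 and 149 CPM in KO P0, 56.3-fold lower (95% counting interval 52.6 to 60.2). At chr9:3000001-3038402 there were 6585 CPM in WT and 54.9 CPM in KO, 120-fold lower (108 to 135), and at chr2:98492576-98497677 there were 4659 and 32.4 CPM, 144-fold lower (125 to 167). Among intervals with a KO read, the most extreme ratio was at chr13:77586939-77587257, with 335 reads in WT and 1 read in KO, 221-fold lower (39.4 to 8758). The interval at chr12:67106104-67106292 had 101 reads in WT and 0 in KO, at least 22.2-fold lower, and the remaining 5 of the 10 were 100.4-fold to 163-fold lower. In all, 12 intervals were at least 16-fold lower in KO, of which 4 were on unplaced scaffolds and 3 within 500 kb of the first deposited interval of their chromosome. Among the 23200 intervals tested at P8, 12 were on scaffolds and 103 that near the first interval. The intervals at least 16-fold lower at P0 came from another set, the 14108 with at least 100 reads, so the shares are not directly comparable. At P8, 8 of the 12 had enough reads to be tested, and 7 of these fell in KO. These 7 summed to 21300 CPM in WT P0 and 250 CPM in KO P0, an 85.1-fold difference. At P8 they summed to 702 ± 30.5 CPM in WT and 56.2 ± 2.05 CPM in KO (SD, n = 2 each), a 12.5-fold difference. Most of the KO sum came from chrUn_JH584304v1:56548-114452, and the other 6 summed to 12920 and 101 CPM at P0, a 128-fold difference, and to 390 ± 10.8 and 4.36 ± 1.57 CPM at P8, an 89.4-fold difference. The exception, chr9:35216470-35275831, was 32.7-fold lower in KO at P0 and had a log2 fold change of 0.45 at P8 (adjusted p 0.0432 in edgeR's quasi-likelihood test with BH adjustment).

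The largest ratio in the other direction at P0 was at chr12:12384184-12384544, with 132 reads in KO and 3 in WT, 66.7-fold higher (95% counting interval 22.3 to 327). The other 9 of the 10 highest ratios lay between 11.7-fold and 29.0-fold. Of these, chr10:62008852-62019480 had 50.4 CPM in KO P0 and 4.10 CPM in WT P0, and was also higher in KO at P8, with 73.8 ± 3.21 against 3.71 ± 0.477 CPM (SD, n = 2 each). Across 7721 intervals measured at both ages, 214 were at least 2-fold higher in KO at both, where independent lists would share 62.0. At both ages 20 were at least 2-fold lower, against 14.6 for independent lists. In opposite directions, 20 were at least 2-fold lower at P0 and higher at P8, and 9 higher at P0 and lower at P8, against 30.7 and 29.5. Across these intervals, which are not independent replicates, the log2 ratios at P0 and P8 had a Pearson correlation of 0.401 and a Spearman correlation of 0.315.

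**Figure D3:**
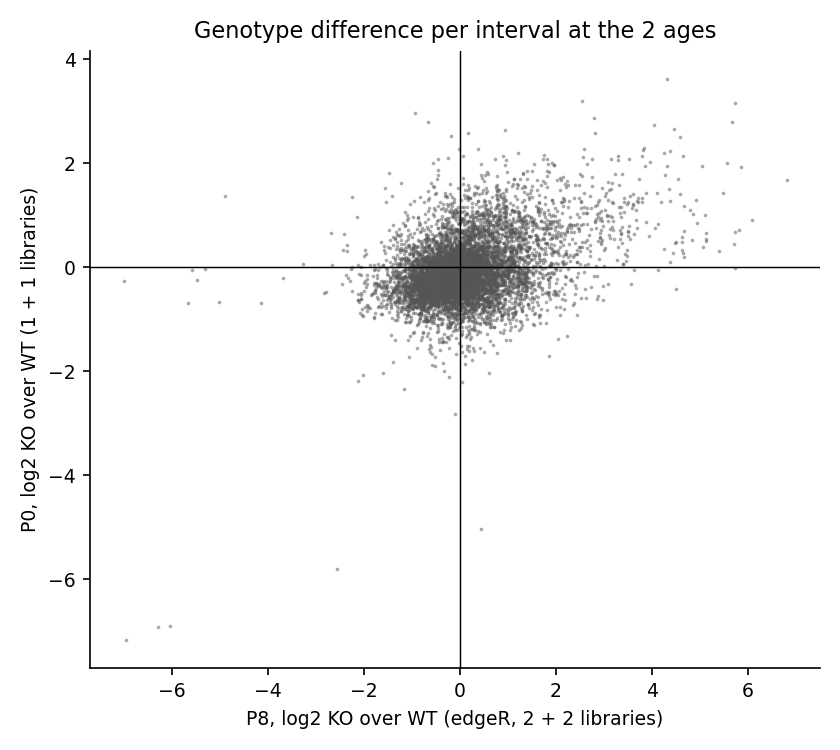
Log2 ratio of KO over WT at P8 (x axis, edgeR, 2 libraries each) against that at P0 (y axis, 1 library each), with 1 point for each of 7721 intervals with at least 100 reads at P0 and a mean of at least 10 CPM at P8. Points at the lower left are intervals lower in KO at both ages, of which 20 are at least 2-fold lower at both, and 214 intervals are at least 2-fold higher in KO at both.

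Levels at P8 were compared with those in the single P0 library of each genotype, whose spread was not measured and was taken from the P8 pairs. In WT, 11090 of 37627 intervals were higher at P8 and 14492 lower, and in KO 9925 were higher and 11764 lower, in edgeR's quasi-likelihood test with BH adjustment. The largest rise in WT was at chr15:74512551-74516001, which had 0 reads in WT P0 and 248 ± 18.0 CPM in WT P8 (SD, n = 2), at least 725-fold higher. The other 4 largest rises in WT, at chr10:75877454-75877743, chr17:27528327-27528579, chr6:56736832-56737339 and chr2:5696415-5698927, also had 0 reads in WT P0 and were at least 217-fold, 96.9-fold, 90.2-fold and 84.0-fold higher. The largest falls in WT included chr9:101302709-101304114, at least 35.1-fold lower, and chr5:3704548-3705275, at least 25.6-fold lower. Intervals at chr6:69364307-69366225 and chr14:8535728-8536469 fell by 279-fold (95% counting interval 49.7 to 11080) and 273-fold (48.5 to 10810).

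In KO, the largest rises were from 0 reads at P0, at chr6:37173125-37202610 (at least 56.4-fold), chr1:160228203-160239400 (54.0-fold), chr3:145289240-145301160 (49.6-fold), chr8:71193743-71194230 (40.2-fold) and chr8:74016337-74040532 (35.9-fold). The largest falls in KO were at chr13:9884449-9884625, chr14:50298548-50300534, chr9:56130809-56131345 and chr13:70072860-70082525, which were 387-fold (95% counting interval 69.0 to 15360), 228-fold (40.4 to 9071), 131-fold (44.5 to 641) and 109-fold (42.0 to 401) lower at P8. The interval at chr16:10961761-10962168 was among the 5 lowest in both genotypes, 167-fold lower in WT (56.8 to 813) and 98.9-fold lower in KO (38.2 to 366). Age is confounded with the cell preparation, and total-count scaling moved the split to 7358 higher and 19877 lower in WT and 6414 and 16922 in KO, with the share of higher calls going from 43.4% to 27.0% and from 45.8% to 27.5% and the median log2 change from -0.47 to -1.23 and from -0.27 to -0.96. DESeq2 called 6152 and 5809 in WT and 5236 and 4652 in KO, and leaving out WT P8 replicate 1 or 2 gave 7512 and 7618 or 7615 and 8040 in WT, and 7132 and 7201 or 7205 and 7282 in KO.

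The interaction of genotype and age rests on 1 P0 library per genotype, whose spread was not measured, and its calls were lost without either WT P8 replicate. With all 6 libraries, the KO against WT difference was called more positive at P8 than at P0 at 1945 of 37627 intervals and more negative at 959 (edgeR's quasi-likelihood interaction test with BH adjustment). The chromosome 17 interval at 27512805 to 27525382 had 15.8 CPM in WT P0 and 13.1 CPM in KO P0 against 1317 and 9.97 CPM at P8, an interaction of -6.77 ± 0.21 (log2, SE). In the other direction, chr14:6586085-6590007 had 3 reads in WT P0 and 1 read in KO P0 against 3.31 ± 0.218 CPM in WT P8 and 108 ± 10.5 CPM in KO P8 (SD, n = 2 each), an interaction of 5.92, which rests on these few P0 reads. The scaffold interval chrUn_JH584304v1:56548-114452 had an interaction of 3.23 ± 0.11, being 56.3-fold lower in KO at P0 and lower by 2.56 on the log2 scale at P8. Without WT P8 replicate 1 or without WT P8 replicate 2, edgeR called 0 in each direction at the adjusted threshold, with 5949 and 5991 intervals at an unadjusted p under 0.05, and with all libraries DESeq2 called 745 and 501 and edgeR without a filter 1030 and 228. Leaving out KO P8 replicate 1 or 2 gave 3082 and 1752 or 3273 and 2024.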

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

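The tests of explanations in this part were chosen after the results had been seen, while the test of the genotype difference between the ages was planned. The genotype difference was tested against age with 1 P0 library per genotype, whose spread was taken from the P8 pairs. With all libraries 1945 intervals were called with a more positive and 959 with a more negative difference between KO and WT at P8 than at P0, and 0 of either without WT P8 replicate 1 or without WT P8 replicate 2. The 5 most positive interactions (log2) were 6.05 at chr2:17756439-17756669, 5.94 at chr16:70340245-70340366, 5.92 at chr14:6586085-6590007, 5.73 at chr9:102369139-102396566 and 5.45 at chr9:35216470-35275831. The last comes from 435 CPM in WT P0 against 13.3 CPM in KO P0, and not from P8. The 5 most negative were -10.2 at chr17:27581941-27583649, -9.33 at chr15:74512551-74516001, -6.77 at chr17:27512805-27525382, -6.53 at chr12:98400785-98409012 and -6.53 at chr9:67623464-67630476. None of the 10 passed the adjusted threshold in edgeR's quasi-likelihood test when WT P8 replicate 1 or WT P8 replicate 2 was left out, although their log2 values stayed between -10.25 and -6.41 or between 5.42 and 6.67. Without a filter, chr15:74512551-74516001 (adjusted p = 0.179) and chr14:6586085-6590007 (adjusted p = 0.0868) also missed it, as did the former with 1 interval per merged region (0.0529), in the same test with BH adjustment. Fitted values of intervals with 0 to 3 reads in a group, chr17:27581941-27583649, chr15:74512551-74516001 and chr14:6586085-6590007 among them, depend on the prior count.

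The 110 intervals at least 4-fold lower in KO at P8 had a median log2 fold change of -2.59 (also -2.59 with groups without a read at their floor). With calls made without WT P8 replicate 2, 88.7% of 115 such intervals were at least 2-fold higher in that left-out library than in WT P0, against a median of 53.0% and at most 70.4% in 10000 random lists matched on the mean level of the 6 libraries, and of 64.3% and at most 79.1% in lists matched on WT P8 replicate 1. In the P0 libraries, which were not in the P8 fit, their median log2 ratio of KO over WT was -0.13 (quartiles -0.56 and 0.20, 40 of 110 higher in KO, percentile 23.0 of lists matched on mean level). This argues against a difference as large as at P8 for most of the 110, but a smaller one at P0 stays open. At P0 7 (6.36%) were at least 2-fold lower, 4 of them among the intervals at least 16-fold lower there. Random lists had a median of 1.82% and a 95th percentile of 5.45%, and the highest list exceeded 6.36%. The 843 intervals at least 2-fold lower at P8 had a median log2 ratio of -0.24 at P0, against -0.097 in matched lists (percentile 0.0). A candidate explanation, a hypothesis from these same data, is that many of the 110 intervals gain small RNA in WT between the ages, while the change with age in KO was not tested apart from the choice of intervals by their low KO P8 level. A different make-up of the KO THY1+ preparation cannot be told apart from it, because 0 rows of the table carry a gene name, and age, cell preparation and the single P0 libraries remain confounded.

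The 432 intervals at least 4-fold higher in KO at P8 had a median log2 fold change of 2.85. In the P0 libraries, which were not in the P8 fit but counted in the choice of the non-overlapping set, 28.2% were already at least 2-fold higher in KO than in WT, against a median of 4.86% and at most 9.26% in 10000 random lists matched on mean level, and the median log2 ratio was 0.60, with 369 of 432 higher in KO. The median log2 ratio of P8 over P0 was -0.90 in WT, against 0.95 in matched lists, and 1.21 in KO, against 1.01. The intervals were chosen by their P8 levels, so these changes with age are no separate test. These values, and those of the lower intervals, were taken after adding 1 CPM to each value. By the P0 ratios, part of the excess in KO may precede P8. This rests on 1 library of each genotype at P0, and a different cell make-up of the KO preparations cannot be told apart from it, because 0 rows of the table carry a gene name.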

How the results depend on the processing

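Alternatives that chose 1 interval per merged region, left out the 100 intervals with most reads, asked for a 2-fold change, or used the deposited log2 values were chosen after seeing the data. Planned analyses of repeat subfamilies, repeat lists and repeat classes were not run, for want of names. For KO against WT at P8, the non-overlapping set gave 3199 higher and 2440 lower with DESeq2, 3516 and 2349 without a filter, and 3569 to 4842 higher and 3029 to 4417 lower with 1 replicate left out. Over all deposited intervals DESeq2 gave 32216 and 26109, no filter 31385 and 24609, and left-out replicates 34031 to 52584 and 28559 to 45080. Asking for a 2-fold change as well gave 3292 and 2111 in the non-overlapping set and 37210 and 27294 over all intervals, which follows from how it is built. With the replicate number as a block the counts were 5712 and 5301 in the non-overlapping set and 60554 and 57253 over all intervals. Same-numbered P8 replicates had a correlation of deviations of 0.36 over 2 pairs. The series' design text speaks of pairs of samples without saying what a pair shares, so whether the number pairs WT with KO is not known. Total counts gave 7358 higher in WT and 6414 in KO for P8 against P0, and DESeq2 gave 6152 higher and 5809 lower in WT and 5236 and 4652 in KO. Left-out replicates gave 7512 to 12004 higher and 7618 to 15602 lower in WT, and 7132 to 10057 and 7201 to 11133 in KO. The genotype by age counts went to 1030 and 228 without a filter, to 745 and 501 with DESeq2 (22614 intervals had no adjusted p), and to 0 to 3273 and 0 to 2024 with left-out replicates. A fit with 1 fewer library has fewer residual degrees of freedom, and a lone library is assumed to vary like the other groups. The interaction calls were lost without either WT P8 replicate but increased without either KO P8 replicate. In the former fits the spread came from the KO P8 pair alone, and in the latter from the WT P8 pair alone. The cause of these and the other shifts was not tested. The other counts of calls under these alternatives stayed within 1.5 times. Of the named intervals, 237 alternative values at P8, 100 over all deposited intervals and 89 for each age contrast kept their direction and stayed past the threshold. For the interaction 66 did and 23 kept the direction but missed the threshold. At P0, 39 stayed within the counting interval and 1 moved outside it. Passing the threshold without a KO P8 replicate or with the replicate block adds little, because adjusted p there was often far smaller than in the main fit. Of 88351 intervals with a read, 23200 had enough reads to be tested at P8. The P8 fit on simulated counts recovered 55% of 2-fold changes and the interaction 10%, which does not separate depth from the number of libraries.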

Other observations

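All tests and groupings in this part were chosen after the results had been seen. Short intervals changed at least 2-fold more often at P8. Of the 650 tested intervals of at most 300 bp, 30.6% were at least 2-fold higher in KO, against 13.7% of the others (Fisher's exact test, BH-adjusted p = 1.06e-26), and 16.2% at least 2-fold lower, against 8.90% (BH-adjusted p = 2.11e-08, both over 10 tests). At any fold, 33.1% of them were higher, against 22.2% of the others, but the share of lower intervals was 20.6% against 20.1%. Of the 8470 intervals over 20000 bp, 12.7% were at least 2-fold higher and 6.68% at least 2-fold lower. Intervals are not independent replicates, so these p-values describe this set of intervals in these libraries. The length groups were not matched on read level, and a long interval sums all reads within it, so the part of length itself was not tested.

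A larger share of the tested intervals was higher in KO on chromosome X than elsewhere. Of its 414 tested intervals 97 (23.4%) were at least 2-fold higher in KO at P8, against 14.0% elsewhere (Fisher's exact test, BH-adjusted over 40 tests, p = 1.46e-05), and the share was 22.0% against 12.8% with total-count scaling. On chromosome 13 it was 18.7% against 14.0% (adjusted p = 0.0022), and no other chromosome passed the threshold in either direction. The share of reads on chromosome X, out of the intervals tested in either fit, was 0.634% and 0.641% in the WT P8 libraries and 0.726% and 0.723% in the KO P8 libraries. At P0 it was 0.839% in WT (exact binomial 95% interval 0.832 to 0.846) and 0.925% in KO (0.916 to 0.934). The deposited intervals themselves were sparse on this chromosome, at 119 per Mb against 391 (chromosome 3) to 746 (chromosome 11) per Mb on the 19 autosomes.

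Of the 12 intervals at least 16-fold lower in KO at P0, the 8 tested at P8 had similar ratios of WT P8 (after adding 0.1 CPM) over WT P0, with an SD of 0.234 (log2) against a median of 1.92 and a 1st percentile of 0.835 in 10000 random lists of as many tested intervals. A single source supplying all reads at all 8 places is argued against, since it would give them 1 KO over WT ratio. Their P8 log2 fold changes included -6.95 at chr2:98492576-98497677, -2.56 at chrUn_JH584304v1:56548-114452 and 0.45 at chr9:35216470-35275831, with a chi-square of 173 per degree of freedom around a common value. Without chrUn_JH584304v1:56548-114452 and chr9:35216470-35275831, the other 6 lay between -8.37 and -6.04, so a source shared by these 6 is not argued against. Nor can the comparison tell a shared source from one mixed with other reads of the same interval. Carry-over of WT P0 reads into the WT P8 libraries would keep every interval at or above their ratio of 2.79% to 4.33%, but 41 of 5754 other intervals with at least 200 WT P0 reads lay below it with the upper counting bound included. A fault of a single P0 library is argued against as the cause for the set as a whole, since 87.5% of the 8 were at least 2-fold lower in KO in the P8 libraries, against a median of 0% and at most 50.0% in random lists matched on the WT P8 level. It stays open, beside a difference between the ages, for chr9:35216470-35275831. Whether some of the 8 share a source was not tested, since the rows carry coordinates alone. Intervals that share a source would not be independent, as the random lists treat them.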
